A study of Homo sapiens with 12 samples.

How the data were processed

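The series holds 12 QuantSeq 3′ mRNA libraries (Lexogen, forward kit, which reads the 3′ ends of polyadenylated RNA) of HEK293 reporter cells, 6 with SUPT4H1 siRNA and 6 with scrambled siRNA, each made from 200 ng of RNA, per the labels' protocols. ERCC standards were diluted 1:100 and 2 μl went into each lysate before RNA extraction, per the labels' protocols. The authors deposited 1 table of raw whole-number counts per gene, with 57704 genes, 92 ERCC standards and 1 row named GFP, which is taken as the reporter transcript. Per the submitters' processing notes, FastQC 0.11.5, STAR (no version given), MultiQC and R 3.4.3 were used with genome build GRCh38.p10. The counting tool, the gene annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. Symbols were taken from the table, where 35522 genes have one, and 29351 genes had no count in any library. Positions and 3′ UTR sequences came from GENCODE release 29 (GRCh38), in which 57447 genes (99.6%) were found by identifier.

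Counts were tested with edgeR 4.0.16 (quasi-likelihood test with robust estimation) in R 4.3.3, SUPT4H1 siRNA against scrambled siRNA over all 12 libraries without covariates, after the default filterByExpr filter, which left 13820 genes. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. For relative abundance, libraries were scaled by TMM over endogenous genes, and CPM are TMM-scaled counts relative to the sum of endogenous counts. For spike-in-scaled abundance, each library was scaled by its summed counts of the 23 ERCC standards of subgroup B, which are at a nominal ratio of 1 between the mixes. The assignment of standards to subgroups was written from general knowledge of the product, without a supplied table, and all spike-in-scaled values rest on it. The other subgroups have nominal mix 1 to mix 2 ratios of 4 (A), 0.667 (C) and 0.5 (D). The GFP row was carried through each fit but entered neither library sizes nor counts of calls. Single values per library were compared by an exact two-sided permutation test over all splits of the 12 libraries into 6 and 6, whose smallest p is 0.0022. The 95% interval of the spike-in ratio came from inverting that test.

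A set of 30 gene lists was fixed before the data were examined, and 28 had at least 3 tested members. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, fry and, added after seeing the data, an exact permutation test of the mean of a list per library as alternatives. Genes named in the text follow a rule fixed before the data were examined: SUPT4H1, SUPT5H, C9orf72 and the reporter, the 12 largest rises and 12 largest falls with an adjusted p under 0.05, at least 5 CPM in a group mean, no overlap between the libraries of both groups and a gene symbol that is not a clone name, then up to 4 called members per list by adjusted p, and members contrasted with them. HSPA5 and PDIA4 are such contrasts, picked after their values were seen. The text names only a part of the genes that this rule takes. Alternatives included DESeq2 1.42.0, limma-voom, other scalings, filters and spike-in subsets, RNA integrity as a covariate, the replicate number as a block, a minimum change of 1.5-fold and leaving out each library. To look for a library deposited more than once, libraries of a group were compared in 30 pairs, and none agreed within sampling noise (chi-square per degree of freedom between 4.45 and 34.7). That the libraries are separate transfections is taken from the labels.

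A scan of 15740 7-base words in the annotated 3′ UTRs of 10069 genes with at least 5 CPM regressed the relative log2 fold change on presence of the word, UTR length and GC content. Scripts were tested on simulated counts drawn from the real means and library sizes. In 13820 simulated genes for the relative comparison, 59.7% of 67 genes planted at 1.5-fold, 85.1% of 67 at 2-fold and 100% of 66 at 4-fold were called, with 10 false calls. For the spike-in-scaled comparison over 13820 genes, 20 simulated data sets with the real spread of spike-ins and no change gave at most 8 calls. A further single draw with no change, in which the simulated spike-ins happened to differ between groups, gave 6883. With a planted log2 fall of 1, the ratio passed 0.05 in 18 of 20 data sets, with a median of 12944.5 calls. A planted length slope of 0.2 was recovered as 0.164 over 13798 genes. Library depth limits the precision for genes near the filter.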

Results

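Messenger RNA 3′ ends were counted in HEK293 cells, an established human embryonic kidney line, that stably carry a repeat-containing reporter made of an endogenous intronic sequence and DARP-EGFP. The cells were transfected with pooled siRNAs against SUPT4H1 or with scrambled siRNAs at 100 nM and lysed after 72 hours. Each group held 6 libraries from 6 separate transfections of 1 starting culture, so p-values describe the spread between transfections of that culture. A fixed volume of ERCC RNA standards had been added to each lysate of 1000000 cells, mix 1 in the scrambled group and mix 2 in the SUPT4H1 group. Counts of endogenous genes summed to between 7337033 and 20269171 per library with scrambled siRNA and to between 6591194 and 11366971 with SUPT4H1 siRNA (exact two-sided permutation test, p = 0.011, adjusted p = 0.018 over 11 measures per library). In a principal component analysis the first component (55.1% of the variance) separated the groups, and on the next one (19.6%) SUPT4H1 siRNA replicate 6 stood at 26.0, apart from its group (−14.2 to −3.84). The RNA integrity number was between 9.6 and 10 in all 12 libraries. The question behind the series was how loss of SUPT4H1 affects transcription of a repeat-containing reporter, and the standards allow the same question for mRNA as a whole.

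SUPT4H1, which encodes the small subunit of the elongation factor DSIF (SPT4), was 8.81-fold lower in the cells that received its siRNAs. Its level was 184 ± 8.95 CPM (SD, n = 6) with scrambled siRNA and 20.8 ± 1.79 CPM (SD, n = 6) with SUPT4H1 siRNA, and every library of one group lay apart from every library of the other. The relative log2 fold change was −3.14 (SE 0.08, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.66e-17). SUPT4H1 (ENSG00000213246) lies on chromosome 17 from 58345175 to 58353093 (GRCh38) on the minus strand, where the annotation also places RNF43 on the same strand and TSPOAP1-AS1 on the opposite one. SUPT5H (ENSG00000196235, chromosome 19 from 39436156 to 39476670), which encodes the large DSIF subunit, had a relative log2 fold change of 0.27 (SE 0.08, adjusted p = 0.0096). With spike-in scaling its value was −0.54 (adjusted p = 0.12).

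A row named GFP, taken here as the reporter transcript because the cells express DARP-EGFP, fell with SUPT4H1 siRNA under both scalings. It was at 101 ± 11.5 CPM (SD, n = 6) with scrambled siRNA and at 57.5 ± 14.6 CPM (SD, n = 6) with SUPT4H1 siRNA, a relative log2 fold change of −0.82 (SE 0.13, edgeR adjusted p = 9.59e-05). All 6 scrambled libraries, at 91.6 CPM or more, lay above all 6 SUPT4H1 libraries, at 80.5 CPM or less. The spike-in-scaled log2 fold change was −1.66 (SE 0.32, adjusted p = 1.53e-05), which leaves 31.7% of the level in the scrambled group. Among 13820 endogenous genes tested, 541 (3.91%) had a lower relative log2 fold change than the reporter. Among the 2675 genes within 2-fold of its level in the scrambled group, 43 (1.61%) did. No reporter without the repeat was among these libraries. An effect of the repeat therefore cannot be told apart from other features of the transgene. C9orf72 (ENSG00000147894, chromosome 9 from 27546545 to 27573866), an endogenous gene with a disease-associated repeat in its first intron, had 7.09 ± 2.56 and 8.45 ± 1.74 CPM (SD, n = 6 each). Its relative log2 fold change of 0.22 (SE 0.21, adjusted p = 0.43) did not exceed the spread between libraries, nor did its spike-in-scaled value of −0.64 (adjusted p = 0.092). The length of its repeat in these cells was not measured here, so these values do not bear on expanded repeats.

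**Figure D1:**
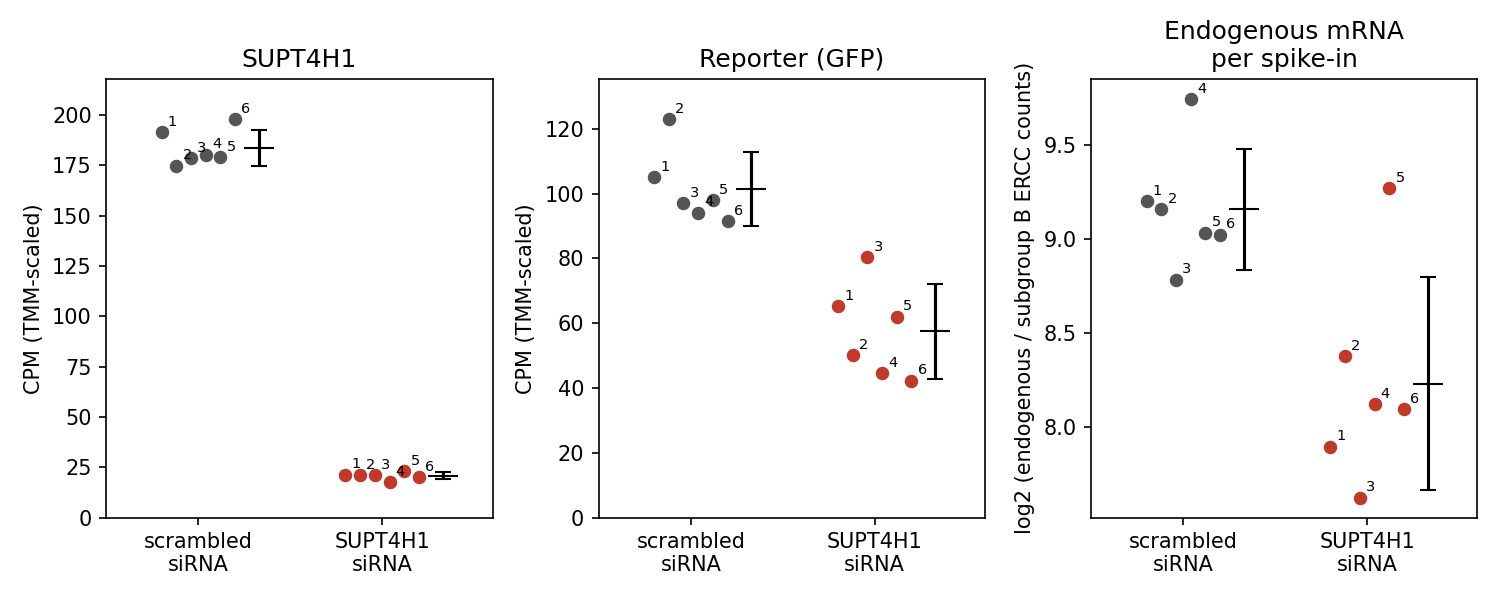
SUPT4H1 and reporter levels (CPM, TMM-scaled) and log2 of the ratio of endogenous to subgroup B ERCC counts in each library, numbered by replicate, with group mean and SD (bars) beside the points. SUPT4H1 and the reporter separate the groups, whereas the ratio of SUPT4H1 siRNA replicate 5 (9.27) lies among the scrambled libraries.

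Less endogenous mRNA was recovered per spike-in from cells with SUPT4H1 siRNA. The log2 ratio of endogenous counts to counts of ERCC subgroup B, the standards at a nominal ratio of 1 between the mixes, was 9.16 ± 0.32 (SD, n = 6) with scrambled siRNA. It was 8.23 ± 0.57 (SD, n = 6) with SUPT4H1 siRNA. The difference of −0.93 corresponds to 52.6% of the level in the scrambled group (exact two-sided permutation test, n = 6 per group, p = 0.013, adjusted p = 0.018 over 11 measures), with a 95% interval of −1.47 to −0.33. ERCC counts made up 0.873% ± 0.169 of all counts in the scrambled group and 1.76% ± 0.573 in the SUPT4H1 group (SD, n = 6 each). After centring on the summed counts of subgroup B, which places B near 0 by construction, the median log2 differences of the other subgroups between the groups lay within 0.021 of their nominal values of −2 (A), 0.58 (C) and 1 (D). The medians of A to D rested on 5, 7, 7 and 7 standards with at least 20 counts in every library. Single standards ran from −0.25 to 0.28 in subgroup B and from 0.19 to 0.91 in subgroup C. With a minimum of 100 counts, chosen after seeing the data, the medians were −2.03 (A), 0.55 (C) and 1.19 (D), and the largest deviation from nominal was 0.19. Mix and group coincide, so a difference in dilution between the mixes would enter this ratio in full. With subgroup C alone the difference was −0.64 (exact permutation p = 0.052).

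With spike-in scaling, 8159 of 13820 genes fell and 42 rose (edgeR quasi-likelihood test, adjusted p under 0.05). The median log2 fold change was −0.82, or 56.7% of the level in the scrambled group, and 95.7% of genes lay below 0. The 42 genes that rose included TTPAL (log2 1.84), GDF15 (1.42), IDNK (1.40) and TMCO1 (1.40). Every gene shares each library's scaling factor, so these calls are not independent of one another. Without SUPT4H1 siRNA replicate 5, whose ratio to the standards lay in the range of the scrambled group, 12340 genes were called, and without scrambled siRNA replicate 4, which had the highest ratio, 5690 were.

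**Figure D2:**
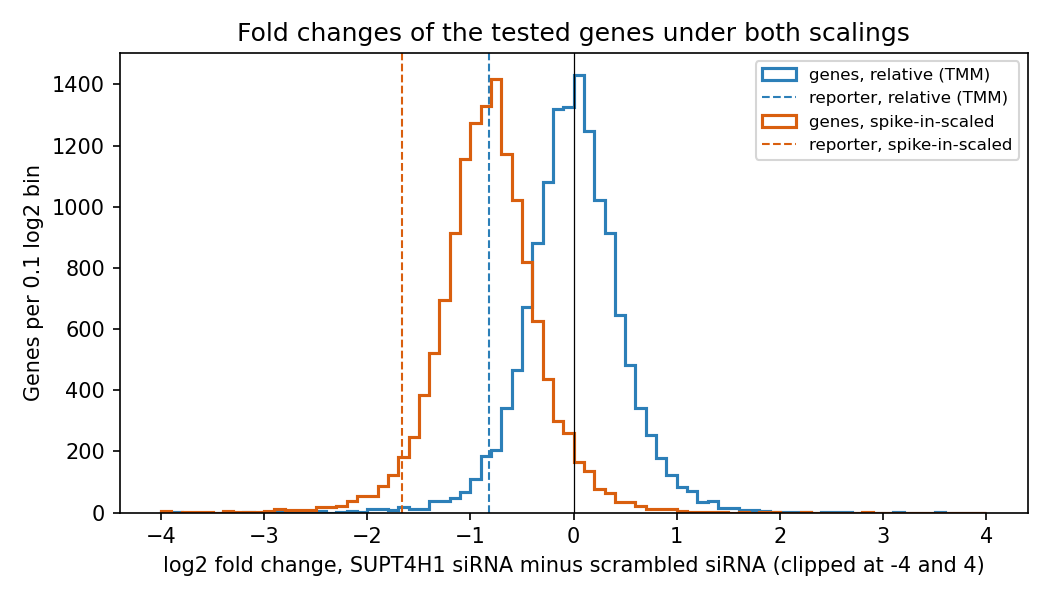
Number of genes per bin of 0.1 in log2 fold change (SUPT4H1 siRNA minus scrambled siRNA) for the 13820 genes tested, with relative (TMM) scaling in blue and spike-in scaling in orange; dashed lines mark the reporter. Spike-in scaling moves the median from 0.00 to −0.82 and the reporter from −0.82 to −1.66.

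In relative abundance, 2806 genes rose and 2734 fell with SUPT4H1 siRNA (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 294 rose and 288 fell by 2-fold or more. The libraries of both groups did not overlap for 2796 genes (20.2% of those tested, against 0.216% by chance). The largest rise among genes with a mean of 5 CPM or more and no overlap was that of TTPAL (chromosome 20 from 44475886 to 44494603), related to the α-tocopherol transfer protein, from 3.04 ± 0.757 to 19.1 ± 3.06 CPM (log2 2.60, SE 0.16, adjusted p = 1.54e-10). TMCO1 (chromosome 1 from 165724293 to 165827755), an endoplasmic reticulum calcium channel, rose from 41.0 ± 3.98 to 189 ± 15.4 CPM (log2 2.21). GDF15, a stress-induced cytokine, rose from 207 ± 63.7 to 919 ± 203 CPM (log2 2.15). The gluconokinase gene IDNK (2.19), TP53I3 (2.04), the growth factor gene MDK (2.03), the autophagy adaptor gene FYCO1 (1.99) and the amino acid transporter gene SLC38A7 (1.85) rose by a similar size. DHRS2 (1.83), the mRNA decay factor gene ZFP36L1 (1.83), the RNA helicase gene MOV10 (1.82) and the phospholipase gene PLA2G16 (1.82) complete the 12 largest rises. TMCO1, TP53I3, FYCO1, MOV10 and PLA2G16 overlap genes on the opposite strand, and without a stated strand setting their values are uncertain to that extent. The annotated 3′ UTRs of 8 of these 12 genes held a match of 7 or more bases to either of the motifs AGCCTT and ACATCA with a fixed flanking base, as did 2 of the 10 largest falls with an annotated 3′ UTR. The motifs were picked by a scan of these same fold changes, so these counts are no independent evidence.

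The falls given here are the largest among genes with a group mean of 5 CPM or more, no overlap between the groups and a gene symbol. After SUPT4H1 came KDF1 (chromosome 1 from 26949562 to 26960406), a keratinocyte differentiation factor. It fell from 8.15 ± 0.961 to 1.18 ± 0.424 CPM (log2 −2.80, SE 0.21, edgeR adjusted p = 2.08e-09). The small GTPase gene RAB39B (−2.74) was next. The fucosyltransferase gene FUT1 (−2.41), the epithelial adhesion gene EPCAM (−2.22) and ARHGAP33 (−2.12) followed. GSTO2 (−1.94), the annexin gene ANXA3 (−1.92), BSPRY (−1.90) and the trypsinogen gene PRSS3 (−1.89) fell by a similar size. EPCAM fell from 21.7 ± 3.81 to 4.61 ± 1.00 CPM. The epithelial cadherin gene CDH1 (−1.21), named as a list member and not by this ranking, fell too. Values of PRSS3, which has near-identical paralogs, and of the small RNA genes RNU5F-1 (−1.99) and SCARNA22 (−1.93), which overlap C1orf228 and WHSC1, are uncertain. EPCAM, ARHGAP33, PRSS3 and CDH1 overlap genes on the opposite strand, and without a stated strand setting their values are uncertain to that extent.

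Genes of the p53 response rose together: 22 of 27 tested targets rose and 0 fell, with a median relative log2 fold change of 0.57, or −0.22 with spike-in scaling (23 rose adjusted over the list alone). Besides GDF15 and TP53I3 (a p53-inducible oxidoreductase), they included BAX, a pro-apoptotic BCL2 family member (1.16), RRM2B, a ribonucleotide reductase subunit (1.15), BTG2 (0.94) and FDXR (0.87). Relative to all genes the list was higher by camera with a preset correlation of 0.01 (adjusted p = 1.84e-11), and adjusted p = 0.040 with an estimated correlation. Cell cycle genes fell. Of 36 G2/M genes 24 fell and 1 rose (median −0.42, the same counts adjusted over the list alone), among them the mitotic kinase gene CDK1 (−0.89), BIRC5 (−0.87), KIF2C (−0.86) and CCNA2 (−0.76). Of 33 G1/S genes 19 fell and 3 rose (median −0.25, with 20 and 3 adjusted over the list alone), among them the replication licensing gene CDT1 (−0.86), E2F1 (−0.75) and the helicase gene MCM3 (−0.58). Both lists were called by camera (adjusted p = 5.20e-11 and 0.00070), with adjusted p = 0.033 and 0.020 with an estimated correlation. Of 18 snoRNA host genes 15 fell and 0 rose (median −0.74, with 16 adjusted over the list alone). SNHG7 fell by 1.66 on the log2 scale, TAF1D by 0.98 and SNHG6 by 0.98. That list had camera adjusted p = 7.40e-19, and adjusted p = 0.0070 with an estimated correlation.

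Of 17 heat shock genes 9 rose and 0 fell (median 0.27, or −0.54 with spike-in scaling, 10 adjusted over the list alone), including HSPB1 (0.80), HSPH1 (0.63) and DNAJA1 (0.55), with camera adjusted p = 0.0011 and adjusted p = 0.048 with an estimated correlation. Of 29 genes of the unfolded protein and integrated stress responses, 16 fell and 8 rose (17 and 8 adjusted over the list alone). The transcription factor genes ATF4 (−1.30) and DDIT3 (−1.06) and the cystine transporter gene SLC7A11 (−1.38) fell. MANF (0.98), the chaperone gene HSPA5 (0.60) and the disulfide isomerase gene PDIA4 (1.08) rose. HSPA5 and PDIA4 were picked after their values were seen, and no part of the list was tested by itself. This list was called as lower (median −0.54, camera adjusted p = 0.0026), with adjusted p = 0.48 with an estimated correlation, and with camera adjusted p = 0.016 without SUPT4H1 siRNA replicate 6. Of 79 cytosolic ribosomal protein genes 48 fell and 1 rose (median −0.34, with 49 and 1 adjusted over the list alone), for example RPS3A (−0.83), RPSA (−0.80) and RPL21 (−0.77), which share sequence with many pseudogenes. Their camera adjusted p was 9.21e-09, and adjusted p = 0.58 with an estimated correlation. Of 13 mitochondrially encoded mRNAs 9 rose and 0 fell relative to all genes (median 0.47, or −0.36 with spike-in scaling, the same counts adjusted over the list alone), including MT-ND5 (0.87), MT-ND4 (0.61) and MT-CO1 (0.60). Their share of all endogenous counts with the other mitochondrial genes was 2.81% ± 0.34 with scrambled siRNA and 3.61% ± 0.36 with SUPT4H1 siRNA (SD, n = 6 each). The camera adjusted p of this list was 0.0013, with adjusted p = 0.48 with an estimated correlation. Of 23 immediate early genes 13 rose and 2 fell (median 0.51, or −0.30 with spike-in scaling, with 15 and 2 adjusted over the list alone), with JUNB at 1.14, IER3 at 0.98 and ATF3 at −0.81. Camera gave adjusted p = 0.00024, with adjusted p = 0.31 with an estimated correlation. Relative changes of all lists are to be read against a shift of −0.82 in the median of all genes under spike-in scaling.

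**Figure D3:**
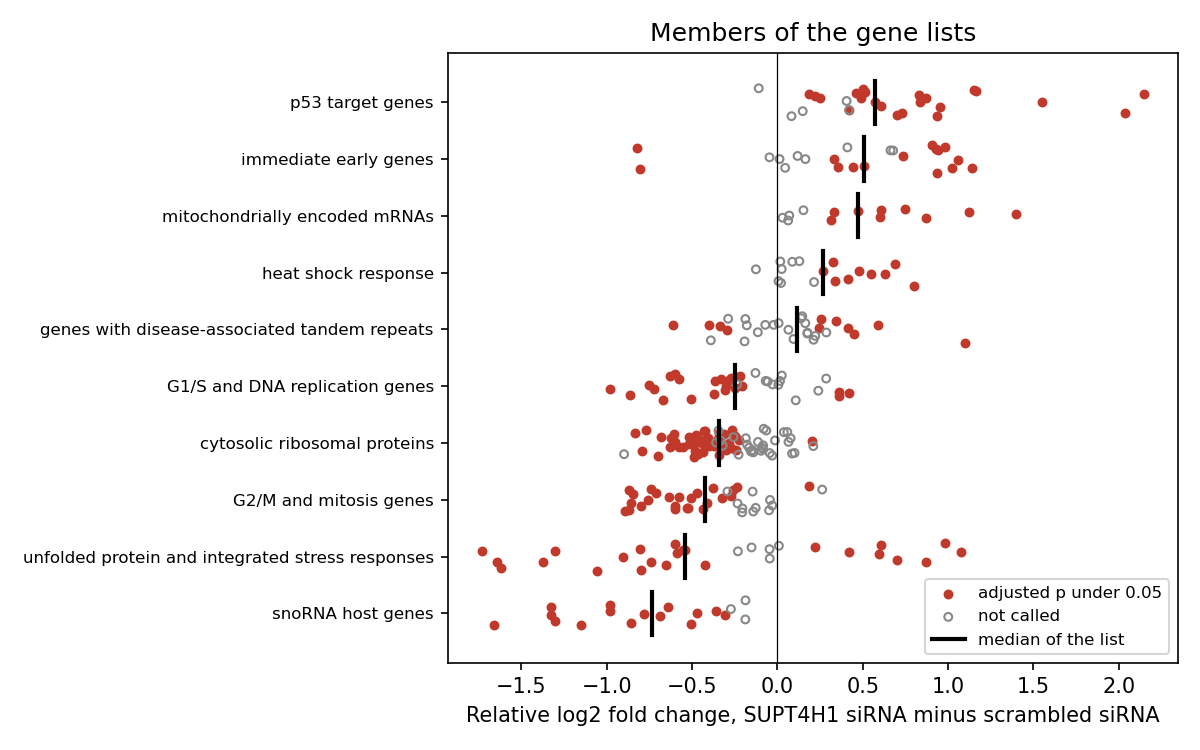
Relative log2 fold change (SUPT4H1 siRNA minus scrambled siRNA) of each tested member of the 9 called lists and of the genes with disease-associated repeats, with filled points at an adjusted p under 0.05 and a bar at the median. Medians run from −0.74 for snoRNA host genes to 0.57 for p53 targets, or from −1.57 to −0.22 for these lists with spike-in scaling.

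The other lists were not called by camera (adjusted p from 0.059 to 0.88). Of 30 genes with disease-associated tandem repeats 7 rose and 4 fell (median 0.12, or −0.71 with spike-in scaling), with HOXD13 at 0.45, SOX3 at 0.59, GIPC1 at 0.41 and ATXN1 at −0.61. Repeat lengths of these genes were not measured here. Of 34 pausing and elongation factor genes 6 rose and 5 fell, with SUPT4H1 among the latter. The NELF subunit genes NELFA (−0.49) and NELFB (−0.46) fell and MLLT3 (0.55) rose. The median of this list was 0.05, its mean −0.02 and its direction by camera down. In the small RNA pathway 4 of 13 genes rose and 3 fell, with DROSHA at 0.94 and TNRC6B at 1.03. RNA polymerase II subunits numbered 4 risen and 2 fallen of 12, polymerase I and III subunits 5 and 7 of 20, and general transcription factors and Mediator 12 and 6 of 36 (13 and 6 adjusted over the list alone). Splicing components numbered 10 risen and 7 fallen of 37 (11 and 7 adjusted over the list alone), cleavage and polyadenylation factors 5 and 3 of 20, and mRNA decay factors 6 and 10 of 47 (6 and 9 adjusted over the list alone). The decay factors had a median of −0.03 and a mean of 0.00. Nuclear-encoded respiratory chain genes numbered 5 risen and 15 fallen of 52, glycolysis and hypoxia genes 2 and 11 of 27, and cholesterol genes 9 and 5 of 23 (9 and 6 adjusted over the list alone). BCL2 family and caspase genes numbered 8 and 8 of 25, interferon-stimulated genes 5 and 3 of 23 (4 and 3 adjusted over the list alone), NF-κB targets 1 and 1 of 8, and replication-dependent histones 4 and 2 of 19. Markers of other cell types were mostly below the filter. Of those tested, 2 of 10 epithelial markers rose and 4 fell (3 and 4 adjusted over the list alone), and 0 of 6 neuronal markers rose and 3 fell. Fibroblast markers numbered 3 risen and 0 fallen of 5 (3 and 1 adjusted over the list alone), endothelial markers 1 and 0 of 2 (1 and 1 adjusted over the list alone) and leukocyte markers 1 and 0 of 1.

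Genomic gene length, a property of interest for an elongation factor, was weakly related to the relative change across 13798 genes. The Spearman correlation across genes was 0.06, and genes are not independent replicates. The slope per 10-fold of length was 0.04 ± 0.06 (SD, n = 6) in SUPT4H1 libraries against 0 ± 0.03 in scrambled ones, which did not exceed the spread between libraries (exact two-sided permutation test, n = 6 per group, p = 0.19, adjusted p = 0.38 over 4 versions of the test). Medians ran from −0.04 in the fifth of genes with the shortest length to 0.03 in that with the longest. With the length of the longest transcript in place of genomic length the correlation was 0.17 and the slopes were apart (exact permutation p = 0.0022, the smallest possible here, adjusted p = 0.0087).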

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

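The tests of spike-in volume, mix dilution and cell number were chosen only after the result was seen, and the counts over other splits were planned. Of 150 sets of 6 values examined, 5 held a library farther from the others than the 95% critical value of Dixon's ratio allows, where chance gives about 7.5. Scrambled siRNA replicate 4, the library with the fewest counts in its group, had 18931 genes with a count against 20877 to 21867 in the others, 2.18% of counts from mitochondrially encoded genes against 2.83% to 3.19%, and MT-ND4 at 1128 CPM against 1512 to 1778 CPM. RAB39B was at 3.75 CPM in SUPT4H1 siRNA replicate 6 against 0.955 to 1.63 CPM. DNAJA1 was at 215 CPM in SUPT4H1 siRNA replicate 4 against 178 to 191 CPM.

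The lower endogenous mRNA per spike-in, by 1.90-fold, is set against 3 technical explanations. Uneven spike-in volumes that follow no group would seldom give such a difference (exact permutation p = 0.013), although SUPT4H1 siRNA replicate 5 went against its group. Unequal dilution of the mixes cannot be told apart from an effect of the siRNAs, since each mix was used in 1 group, and would need a 1.90-fold error. Fewer cells per lysate cannot be told apart either, since they would lower every transcript per spike-in by 1 factor. The mitochondrially encoded mRNAs had a median log2 change of −0.36 per spike-in, between 0 and the median of all genes. Of these 13 mRNAs 3 fell, 0 rose and 3 had values above 0. They also rose relative to all genes (median 0.47), so their values cannot decide on cell number. A fall in mRNA per cell after loss of SUPT4H1 stays open as the biological explanation.

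In 100 of the 462 splits of the 12 libraries into 6 and 6, the real one included, only the real split gave as many as 5540 genes changed in relative abundance (highest other 1417). This argues against chance for that count, as far as 100 drawn splits can show. For spike-in scaling 3 of 100 splits, the real one included, gave 8201 genes or more (highest other 11832). The share is under 0.05, but all genes share each library's scaling factor, so this count cannot exclude chance. The split with 11832 exchanged SUPT4H1 siRNA replicate 5 and scrambled siRNA replicate 6, so such counts follow the spike-in ratios of single libraries. For gene lists 10 of 100 splits, the real one included, gave 9 called lists or more (highest other 11). The others exchanged only 1 or 2 libraries of each group and so kept most of the real grouping. This count therefore cannot decide on chance for the number of lists called by camera with the preset correlation. In the exact permutation test of per-library means, chosen after seeing the data, each of the 9 lists had p of 0.0043 or less. The 9 lists were picked on these same libraries. Lists that camera did not call also passed, such as general transcription factors and Mediator (difference 0.08, exact permutation p = 0.0022). The values argue against chance in the grouping of libraries for each list, but do not set the 9 apart from other lists.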

How the results depend on the processing

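The genes without motif cores, the higher ERCC minimum, list counts without each library and the per-library list mean were chosen after seeing the data. Relative calls ranged from 4287 to 5852 over the other scalings, filters, tools and covariates, and from 5044 to 5902 without 1 library. They were 535 with a minimum change of 1.5-fold, a stricter test. They were 2077 among genes with an annotated 3′ UTR and neither motif core, where fewer genes were tested. Library size alone gave 3139 risen and 2405 fallen genes. Spike-in-scaled calls ranged from 6785 to 9912 over the other settings and from 5690 (without scrambled siRNA replicate 4) to 12340 (without SUPT4H1 siRNA replicate 5). Endogenous mRNA per spike-in differed by −0.64 with subgroup C alone (exact p = 0.052, the cause was not tested) and by −0.81 to −1.13 without 1 library. Libraries of equal number did not deviate together (correlations from −0.45 to 0.13), so the numbers are not taken as pairs. With a replicate block the difference was −0.93 (exact sign-flip p = 0.062), 4808 genes changed in relative and 9373 in spike-in-scaled abundance, and 9 lists were called. Lists called numbered 5 with an estimated correlation, 18 with fry and 17 with the exact permutation test of per-library means, which included all 9. They numbered 6 among genes with neither motif core, where the stress response list had camera adjusted p = 0.67. That set held only genes with an annotated 3′ UTR, so it left out MT-ND5, MT-ND4, MT-CO1, SNHG7 and SNHG6 among others. Its lower count can in part follow from this. Other causes were not tested. The length trend passed the threshold with transcript length (0.17). Of 67 named genes, 67 kept direction and side of the threshold in each of the 5 relative alternatives run for them (the DESeq2 test, DESeq2 size factors, library size alone, RNA integrity as a covariate and the replicate block). Most were picked from these same counts for large separated changes or small adjusted p-values, so this outcome was largely given in advance. Spike-in scaling, under which the median of all genes was −0.82, left 44 of the 67 named genes on the same side. It ended the call of 11 in the same direction, namely RRM2B (0.38), BAX (0.35), BTG2 (0.15), FDXR (0.06), MT-ND5 (0.04), IER3 (0.17), JUNB (0.33), MANF (0.18), PDIA4 (0.28), DROSHA (0.14) and TNRC6B (0.21). It changed the sign of 12, namely SUPT5H (−0.54), C9orf72 (−0.64), MT-ND4 (−0.21), MT-CO1 (−0.24), HSPB1 (−0.0038), DNAJA1 (−0.31), HSPH1 (−0.22), HSPA5 (−0.20), MLLT3 (−0.24), GIPC1 (−0.44), SOX3 (−0.23) and HOXD13 (−0.41). A change of sign is not a call as lower. For example, the spike-in-scaled edgeR adjusted p was 0.092 for C9orf72, 0.12 for SUPT5H and 0.20 for GIPC1. C9orf72 was not called in relative abundance either (adjusted p = 0.43).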

Other observations

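The tests of motif sites, the p53 test among genes without motif cores and the per-library means of the p53 targets were chosen only after the result was seen. The counts by gene class in this paragraph were looked at after the values were seen, without a test of the class. Of 12 tested snoRNA genes 7 fell and 1 rose (median log2 fold change −1.01), and of 7 scaRNA genes 6 fell and 0 rose (median −2.45). These RNAs lie within introns of other genes and end without long poly(A) tails, so counts over them can come from host transcripts. Of 355 tested processed pseudogenes 71 fell and 10 rose, where of all 13820 tested genes 2734 fell and 2806 rose. Few rises, and not a larger share of falls, set this class apart.

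The rise of genes with AGCCTT or ACATCA motifs in the 3′ UTR was the strongest signal among 15740 words of 7 bases. AGCCTTA had z = 11.5 and CACATCA z = 8.33, against 3.55 as the highest after shuffling fold changes over genes. AAGCCTT, the same core after an A, came second (z = 9.26), above TAGCCTT (z = 8.27). The site counts among the largest rises and falls took only T as the base before this core. Words without either core, such as TTTTTTT (z = 7.63), also passed the shuffled value. To keep picking apart from testing, the genes were split at random into sets of 5034 and 5035. Words were picked in each set and scored in the other, in the same libraries. Both sets picked AGCCTTA first, and CACATCA next once words that overlap AGCCTTA were passed over. UTR length and base composition are argued against as the whole cause, since in the held-out genes AGCCTTA had z = 8.35 and 7.84 against at most 3.36 and 4.13 for 588 words of its composition, and CACATCA had z = 5.54 and 6.15 against at most 3.29 and 2.17 for 126 words of its composition. Held-out genes with either word differed from others in log2 fold change by 0.146 (SE 0.0151) and 0.137 (SE 0.0151) in 3′ UTRs, by 0.0384 (SE 0.0156) and 0.0645 (SE 0.0153) in coding sequence and by −0.0108 (SE 0.0149) and −0.0371 (SE 0.0145) for the reverse complements in 3′ UTRs. This is consistent with a hypothesis of seed-type target sites of transfected siRNAs that lower these transcripts in the scrambled libraries, but the siRNA sequences are not in the labels and no untransfected libraries were analysed here, so a change in an endogenous small RNA after loss of SUPT4H1 stays untested.

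The rise of p53 target genes was weighed against 3 technical explanations. The mean of the targets per library was higher by 0.70 with SUPT4H1 siRNA, in 6 of 6 libraries above all scrambled ones (exact permutation p = 0.0022, the smallest possible, adjusted p = 0.0055 over 28 lists), and camera with the preset correlation gave p = 1.03e-12 with RNA integrity as a covariate and at most 7.43e-12 without 1 library. Motif sites are argued against as the whole cause, since among genes with neither core 9 of 12 targets rose and 0 fell (median 0.78, camera p = 4.32e-09, exact permutation p = 0.0022 for a difference of 0.85). RNA integrity and a single library are argued against by these fits and by the size of the difference, which was 0.70 over the 6 scrambled and 4 SUPT4H1 libraries with a number of at least 9.9 and between 0.67 and 0.72 without 1 library. A response to loss of SUPT4H1 and a response to the siRNAs themselves remain open as hypotheses, since no separate siRNAs were compared here.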
